A study of Oryza sativa Japonica Group and Oryza sativa Indica Group with 20 samples.

How the data were processed

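RNA was measured in 10 libraries, 1 per stage (embryo, callus induction, subculture, successful and failed regeneration) and cultivar (TNG67 and IR64), made from 100 ng of RNA, per the labels' protocols. Per the labels, the authors checked reads with FastQC, mapped them with Bowtie to the japonica Nipponbare genome IRGSP-1.0 with at most 2 mismatches, kept unique alignments, and made FPKM values per locus with TopHat. FPKM is a fragment count scaled to the length of the gene and to the number of mapped fragments of the library. Tool versions, the gene models behind the locus identifiers and the strand setting are not given in the sources used here. Unique alignment removes reads of near-identical gene copies, and mapping an indica cultivar to a japonica genome can lose reads at loci that differ in sequence. The labels also give a 4-fold cutoff for differential expression.

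The deposited FPKM table had 55166 rows for 54170 loci. Rows of the 968 loci present on 2 or 3 rows were summed, a choice made after the data were examined, and an alternative left those loci out. Depth was unknown: ratios of low values (up to 0.2 FPKM) piled up at a common step, with over 10% in 1 bin, for 3 of 45 pairs of libraries, which gives relative depth at most (1.09 for IR64 T2 over T1), and whole reads could not be recovered without the gene lengths the authors used. A value of exactly 0 can be a failed estimate, so such loci are described as listed at 0.

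The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with cultivar and stage as additive terms, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment within each comparison at 0.05. Loci with at least 1 FPKM in at least 2 libraries entered, 22913 in all. As each cultivar and stage has 1 library, the 4 residual degrees of freedom come from the departure of the cultivars from a common stage effect. Nothing in the labels says how many cultures stood behind a library, and they give no batch. Within a cultivar, loci with an (FPKM + 1) ratio of at least 4 were counted with no p-value. Changes in the cultivars were correlated across loci, and the expected overlap of independent lists is the product of their sizes over the loci tested. Overlaps of loci high in failed callus were also set against an expectation matched on level in 20 bins. Other calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and matplotlib 3.10.9 for plots.

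The stage served as the pairing of the cultivars. Deviations from the cultivar means correlated between cultivars at 0.56 for T0, 0.46 for T1, 0.23 for T2, -0.01 for TS and 0.27 for TF. The test was tried on simulated data with 200 of 22913 loci changed. Each stage change was the same in both cultivars, and the noise of a locus had the same spread in every library. At 4-fold it recovered 17 of 50 for T1 against T0, 17 of 50 for TS against TF and 33 of 50 for TNG67 against IR64; at 16-fold it recovered 38, 33 and 47. Of 22713 unchanged loci it called 1, 7 and 3.

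Before the data were examined, 38 gene lists and 34 single genes had been fixed, to be matched by product name. The deposited table pairs its identifiers with no names, and the RefSeq table used here (assembly ASM3414082v1) matched 1 of 54170 identifiers, so no list or single gene could be matched and none of the list tests was run. Loci are therefore given by identifier and by the chromosome it encodes, without names or coordinates. The rule for named loci, fixed beforehand, took loci past the test with an (FPKM + 1) ratio of at least 4 in the same direction in both cultivars (for the cultivar comparison, in at least 4 of 5 stages) and a mean of at least 10 FPKM in the higher group, ranked by fitted change, and filled short lists with the largest change shared by both cultivars, said not to pass. Its condition of a product name was dropped and the number cut to 2 each way after the names proved missing.

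Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, no replicate block, no intensity trend, a robust spread, each library left out in turn, and a 2-fold cutoff. Fits on the 8 calli alone, loci on a single row, the comparisons of TS and TF with T2, and the overlap, position and cultivar-only measurements were added after the data were examined. The 10 bisulfite libraries were not analysed here.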

Results

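The series followed rice through tissue culture, from the embryo to calli placed on regeneration medium, in a japonica cultivar, Tainung 67 (TNG67), and an indica cultivar, IR64. A callus is a mass of dividing, largely unorganised plant cells. RNA was sequenced at 5 stages in each cultivar: the embryo (T0), callus induced on auxin medium (T1), callus subcultured on fresh medium of the same kind (T2), callus that regenerated (TS) and callus that failed to regenerate (TF). T1 and T2 were grown with 2.5 mg/L of the synthetic auxin 2,4-D. TS and TF were on a medium with 0.02 mg/L of the auxin NAA and 2 mg/L of the cytokinin BAP. Each stage of each cultivar was represented by 1 RNA library, 10 in all, so no value below has a replicate of its own cultivar and stage. The 10 bisulfite libraries of the series were not analysed here.

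The deposited values were FPKM for 54170 loci, of which 22913 had at least 1 FPKM in at least 2 libraries and were tested, and 18238 were listed at 0 in all 10 libraries. Sequencing depth was unknown, because the values are not counts. Summed FPKM ran from 602209 in the IR64 T2 library to 1063010 in the TNG67 embryo, with the IR64 embryo at 3792960. In that embryo library the 10 most abundant loci held 81.6% of the sum. LOC_Os12g13870 on chromosome 12 stood at exactly 3000000 FPKM, 79.1% of the sum, after its 2 deposited rows were added. A round value of that size can be a failed estimate. Without it the sum was 792962 and the 10 most abundant loci held 12.8%. In the calli the most abundant locus was LOC_Os01g15270 in all libraries except IR64 TF, at 27387.6 to 62308.3 FPKM. LOC_Os09g01000 was listed at 0 in the IR64 T2 library and at 6432.2 to 13833 in the other libraries. These 3 loci were singled out after their values were seen.

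The first principal component, with 46.2% of the variance, separated the calli of the cultivars, and the second, with 28.5%, separated the embryos from the calli. Within each cultivar the successful callus resembled the subcultured callus more closely than the failed callus did. The Pearson correlation across loci between T2 and TS was 0.972 in TNG67 and 0.978 in IR64, against 0.919 and 0.914 between T2 and TF. The TNG67 TF library correlated with the 4 IR64 calli at 0.819 to 0.823, and the other TNG67 calli did so at 0.698 to 0.777. Loci are not independent replicates, so these correlations describe the libraries and carry no p-value.

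**Figure D1:**
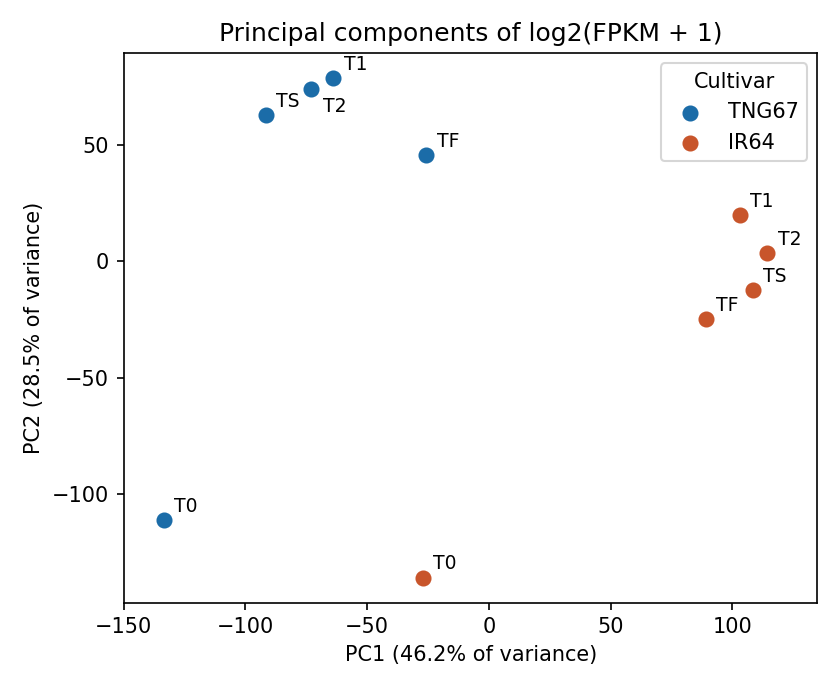
Principal components of log2(FPKM + 1) over the tested loci, each point 1 RNA library, labelled by stage and coloured by cultivar. The axes hold 46.2% and 28.5% of the variance, the embryos (T0) lie apart from the calli, and the TNG67 TF library lies nearer to the IR64 calli on the first axis than the other TNG67 calli do.

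Callus induction is the first comparison the design names. Between T1 and T0, 2676 loci rose and 3347 fell under an effect common to both cultivars, and 773 of the risen and 1341 of the fallen loci had a fitted change of at least 4-fold. The balance turned after quantile normalization, with 2813 higher and 2656 lower. LOC_Os03g46640 on chromosome 3 rose from 4.433 to 537.919 FPKM in TNG67 and from 6.097 to 700.933 in IR64, a log2 change of 6.63 (SE 0.41, limma adjusted p = 0.0019). LOC_Os03g03724, also on chromosome 3, rose by 6.59 on the log2 scale (SE 0.9, limma adjusted p = 0.0062), with 8.34 in TNG67 and 4.85 in IR64. LOC_Os08g03410 on chromosome 8 fell from 5240.43 FPKM to a listed 0 in TNG67 and from 22354.5 to 15.375 in IR64. LOC_Os11g37270 on chromosome 11 fell from 666.836 to 0.027 FPKM in TNG67 and from 5934.54 to 0.221 in IR64. The log2 changes across loci in the cultivars correlated at 0.57 (Pearson). Loci at least 4-fold higher numbered 1358 in TNG67 and 1574 in IR64, with 514 in both against 93.3 for independent lists. Loci at least 4-fold lower numbered 2110 and 1976, with 875 in both against 182. These expectations were not matched on level, so levels that the cultivars share can raise the overlaps. The IR64 balance turned with a pseudocount of 0.1 (3163 higher and 2851 lower) and at 2-fold (5084 and 4721), and the TNG67 balance did not (2855 and 3003, 4148 and 5276).

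All fold changes are on the log2(FPKM + 1) scale, which understates changes of low loci. limma's adjusted p rests on the departure of the cultivars from a common stage effect (4 residual degrees of freedom), so it measures whether both cultivars moved alike and not the spread between cultures. The T1 count of 6023 fell to 2165 without the TNG67 T1 library, 1439 without IR64 T1, 3798 without TNG67 T2, 3813 without IR64 T2 and 2504 without the cultivar term as replicate block.

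Subcultured callus (T2) also differed widely from the embryo, with 1907 loci higher and 2801 lower. LOC_Os06g48250 on chromosome 6 was listed at 0 in the TNG67 embryo and 0.321 FPKM in the IR64 embryo, and rose to 42.693 and 125.015 in the T2 calli (limma adjusted p = 0.0036). LOC_Os03g03724 was at 544.92 FPKM in TNG67 and 160.727 in IR64 (limma adjusted p = 0.0073, but 0.072 without TNG67 T2 and 0.065 without IR64 T2). LOC_Os08g03410 and LOC_Os11g37270 stayed low, the first at a listed 0 in TNG67 and 16.129 FPKM in IR64, the second at 0.046 and 2.35 (limma adjusted p = 0.0036 for LOC_Os11g37270, but 0.052 without TNG67 T2). The changes in the cultivars correlated at 0.48 across loci. The count of 4708 fell to 60 without TNG67 T2, 254 without IR64 T2, 3001 without TNG67 TS, 3017 without IR64 TS and 1509 without the replicate block.

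In successful calli (TS) 1457 loci were higher and 2098 lower than in the embryo. LOC_Os03g03724 stood at 638.947 FPKM in TNG67 and 90.892 in IR64, against 1.238 and 2.438 in the embryos (limma adjusted p = 0.012, but 0.086 without TNG67 TS and 0.074 without IR64 TS). LOC_Os06g48250 stood at 34.592 and 113.251 FPKM (limma adjusted p = 0.0057, but 0.058 without IR64 TS). The changes in the cultivars correlated at 0.4. The count of 3555 fell to 0 without IR64 TS, 38 without TNG67 TS, 1366 without TNG67 T2, 1368 without IR64 T2, 2203 without TNG67 T1, 2228 without IR64 T1 and 712 without the replicate block. A limma count of 0 here rests on a single library for TS, assumed to vary like the other stages.

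In failed calli (TF) 1631 loci were higher and 2562 lower than in the embryo under the common effect. Loci at least 4-fold higher and lower numbered 1332 and 1696 in TNG67 and 1503 and 1081 in IR64. This balance depended on the setting, with 3062 and 2326 in TNG67 and 2836 and 1681 in IR64 at a pseudocount of 0.1, 381 and 1011 and 546 and 587 at a pseudocount of 5, and 1250 and 1245 in TNG67 after quantile normalization. LOC_Os01g52240 on chromosome 1 rose from 0.945 to 542.966 FPKM in TNG67 and from 2.199 to 349.04 in IR64, a log2 change of 7.45 (SE 0.69, limma adjusted p = 0.0053). LOC_Os10g11500 on chromosome 10 was listed at 0 in both embryos and at 97.881 FPKM in TNG67 TF and 269.698 in IR64 TF (limma adjusted p = 0.035). It was at 2.973 to 3.188 FPKM in the other TNG67 calli, but at 242.981 in IR64 T2 and 371.915 in IR64 TS, so in IR64 its level was not particular to failed callus. Its call was lost in 6 of 14 settings, with limma adjusted p of 0.14 without the replicate block, 0.19 without TNG67 TF, 0.093 without IR64 TF, 0.11 without IR64 T0 and 0.056 without TNG67 T1 or IR64 T1, over a range of 0.015 to 0.19. The changes in the cultivars correlated at 0.64, the highest value among the comparisons with the embryo. In both cultivars 605 loci were at least 4-fold higher, against 87.4 for independent lists, an expectation not matched on level. The TNG67 TF library was also closer to the IR64 calli (correlations of 0.819 to 0.823) than the other TNG67 calli were (0.698 to 0.777). These values do not separate the agreement of the changes from that closeness. The count of 4193 fell to 266 without TNG67 TF, 1236 without IR64 TF, 1809 without TNG67 T2, 1836 without IR64 T2, 2324 without TNG67 TS, 2325 without IR64 TS, 2659 without TNG67 T1, 2676 without IR64 T1 and 918 without the replicate block.

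Successful and failed calli shared a medium and differed in outcome, and this comparison asks which transcripts went with the outcome. No locus passed limma's test. It called 0 loci, with 960 at an unadjusted p under 0.05 where 1146 are expected by chance, a lowest adjusted p of 0.889, and 1 locus called without the filter on low values; no other tool was run. On simulated data the same test recovered 17 of 50 loci changed by 4-fold, 40 of 50 by 8-fold and 33 of 50 by 16-fold in this comparison. The simulated changes were the same in both cultivars and the noise of a locus alike in all libraries, which need not hold here. The 0 calls therefore do not exclude shared changes of these sizes. Within each cultivar, however, many loci differed between these single libraries. In TNG67 138 loci were at least 4-fold higher in TS and 556 at least 4-fold higher in TF, and in IR64 the numbers were 101 and 613. Of the TF-high loci 30 were common to the cultivars, against 14.9 for independent lists, an expectation not matched on level. Of the TS-high loci 2 were common, against 0.608. Loci at least 4-fold in opposite directions in the cultivars numbered 42, and no expectation was computed for these. The 30 are therefore not read as a pattern shared by the cultivars. The changes correlated at -0.05 across loci.

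Among loci that differed alike in both cultivars without passing the test, LOC_Os10g40510 on chromosome 10 was listed at 0 in TNG67 TS and 63.327 FPKM in TNG67 TF, and at 18.105 and 348.372 in IR64. LOC_Os10g21670, also on chromosome 10, was at 10.832 and 355.108 FPKM in TNG67 and 26.478 and 409.357 in IR64. In the other direction LOC_Os06g19200 was at 13.706 FPKM in TNG67 TS and 2.038 in TNG67 TF, and at 8.052 and 1.172 in IR64. LOC_Os11g05170 was at 93.041 and 22.065 FPKM in TNG67 and 43.632 and 7.8 in IR64.

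The TF-high loci were set against loci that differed at T2 from the embryo or from the other cultivar, a measurement added after the data were examined. Of the 556 in TNG67, 382 (68.7%) were also at least 4-fold higher in IR64 than in TNG67 at T2, where 72.2 were expected for loci of the same level, and 111 (20.0%) were at least 4-fold higher in the embryo than at T2, against 52.7. Loci at least 4-fold lower in the embryo were in excess too, 38 against 13.6, so the TNG67 excess was not particular to embryo-high loci. Of the 613 in IR64, 266 (43.4%) were higher in the embryo, against 62.7, 35 lower in it, against 21.0, and 202 (33.0%) were higher in TNG67 at T2, against 73.2. Loci at least 4-fold lower in TF than in TS were set against the same lists, with the ratio to the level-matched expectation in brackets. Of the 138 in TNG67, 27 were higher in the embryo, against 11.8 (2.3), 28 lower in it (2.79), and 69 (50.0%) lower in IR64 at T2, against 12.2 (5.65), so the TNG67 embryo-high excess was not particular to TF-high loci. Of the 101 in IR64, 4 were higher in the embryo, against 6.85 (0.584), 43 lower in it, against 9.99 (4.3), and 64 (63.4%) lower in TNG67 at T2 (6.37). No library entered both lists of an overlap, but this does not make the lists independent. The level was taken from T2 and TS, which also entered the lists. The filters used all 10 libraries, so a locus low in T2 and TS was kept only where it was higher elsewhere. The ratios for the TF-high loci moved both ways with the setting, given here for a pseudocount of 0.1, a mean of at least 5 FPKM and a pseudocount of 5. The pseudocount also changed the level bins, so part of its effect can come from how the expectation was built. In TNG67 the embryo-high ratio of 2.11 became 1.09, 0.933 and 4.58, and the ratio of 5.29 for loci higher in IR64 became 1.78, 1.85 and 32.9. In IR64 the embryo-high ratio of 4.24 became 2.41, 2.13 and 8.59, and the ratio of 2.76 for loci higher in TNG67 became 1.26, 1.48 and 10.3. The embryo-low ratio became 1.35, 2.84 and 3.39 in TNG67 (2.8 as reported) and 0.984, 2.62 and 2.78 in IR64 (1.66). With 1 library per stage and cultivar these overlaps have no replicate check.

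**Figure D2:**
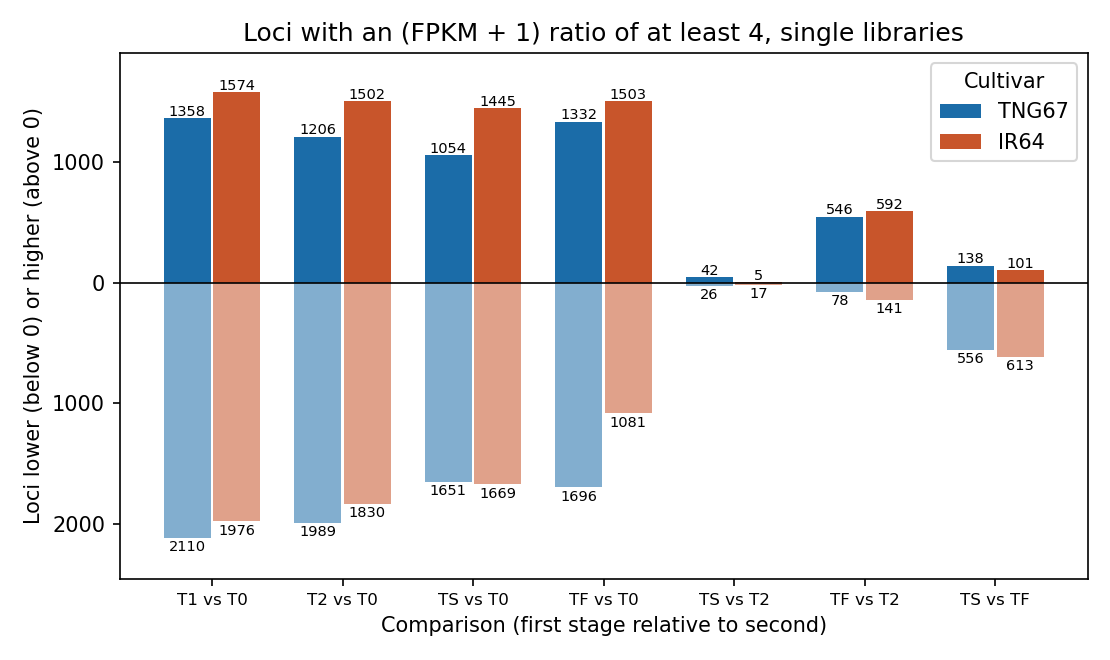
Number of tested loci with an (FPKM + 1) ratio of at least 4 between single libraries, by comparison and cultivar, with loci higher in the first stage above the zero line and lower loci below it. TS differs from T2 at 68 loci in TNG67 and 22 in IR64, and TF differs from T2 at 624 and 733.

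Against the subcultured callus the failed calli had moved further than the successful ones. In TNG67 42 loci were at least 4-fold higher and 26 lower in TS than in T2, while 546 were higher and 78 lower in TF. In IR64 the TS numbers were 5 and 17 and the TF numbers 592 and 141. LOC_Os10g21670 was at 8.613 FPKM in TNG67 T2 and 7.677 in IR64 T2, below its TF values of 355.108 and 409.357. limma called 0 loci for TS against T2 (224 at an unadjusted p under 0.05, 2 called without the filter) and 0 for TF against T2 (1008, and 1). These comparisons were added after the data were examined. For the planned comparison of both regeneration stages with T2 it also called 0 (522 at an unadjusted p under 0.05, 1 without the filter), and for T2 against T1 0 (653, and 2). LOC_Os03g14300 on chromosome 3, at 604.365 FPKM in TNG67 T1 and 72.917 in T2 and at 151.732 and 26.327 in IR64, had an adjusted p of 0.68 in the last of these (limma). All of these counts at an unadjusted p under 0.05 lay below the 1146 expected by chance. The spread of a locus was taken over all stages, the embryo and TF included, so the test can be too strict for calli this similar. The 0 calls therefore do not exclude changes shared by the cultivars.

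The cultivars differed at 6261 loci over the 5 stages, 3211 higher in TNG67 and 3050 higher in IR64. This balance turned after quantile normalization (3134 and 3226) and with median-ratio scaling (3157 and 3181). It also turned on the 8 calli alone (4136 and 4681), where the count rose to 8817. At a mean of at least 5 FPKM it leaned further to TNG67 (1911 and 1523). LOC_Os10g38630 on chromosome 10 was at 459.236 to 1441.23 FPKM in TNG67 and 1.703 to 4.635 in IR64, a log2 difference of 7.88 (SE 0.33, limma adjusted p = 3.7e-05, higher in 5 of 5 stages). LOC_Os12g28015 on chromosome 12 was at 282.774 to 1334.1 FPKM in TNG67 and 0.494 to 12.83 in IR64. LOC_Os02g38750 on chromosome 2 was at 281.821 to 378.863 FPKM in IR64 and 0.02 to 0.952 in TNG67, a log2 difference of -8.04 (SE 0.22, limma adjusted p = 1.6e-05). LOC_Os12g13870, summed over its 2 deposited rows, was at a listed 0 in the 5 TNG67 libraries and at 7026.3 FPKM or more in those of IR64. Reads of both cultivars were mapped to a japonica reference, so this test does not separate a transcript level from how well reads of a cultivar map. It also takes the 5 stages as the replicates of a cultivar, although T1, T2 and TS of a cultivar correlated at 0.934 to 0.978. The adjusted p measures how steady a difference was over these stages, and not the spread between plants or cultures. The count fell to 2430 without IR64 T2, 2438 without TNG67 T2, 2671 without IR64 TS, 2682 without TNG67 TS, 3481 without IR64 T1, 3489 without TNG67 T1, 3434 at a mean FPKM of at least 5 and 3956 without the stage term as block.

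Where the TNG67 failed callus lay between the cultivars was measured, also after the data were examined, on loci that separated the other calli by at least 4-fold. On a scale with 0 at the mean of a library's own cultivar and 1 at that of the other, the TNG67 TF library had a median of 0.19 over 1065 loci, and 21.7% of them lay past the midpoint. Loci high in IR64 had a median of 0.47 and loci high in TNG67 0.13. The other 7 calli had medians of -0.06 to 0.01. In the IR64 TF library the median was 0.0 and 12.7% of 827 loci lay past the midpoint. The T1, T2 and TS calli of both cultivars had 0.146 to 4.01% past it. Part of the loci in IR64 TF thus also lay towards the other cultivar.

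**Figure D3:**
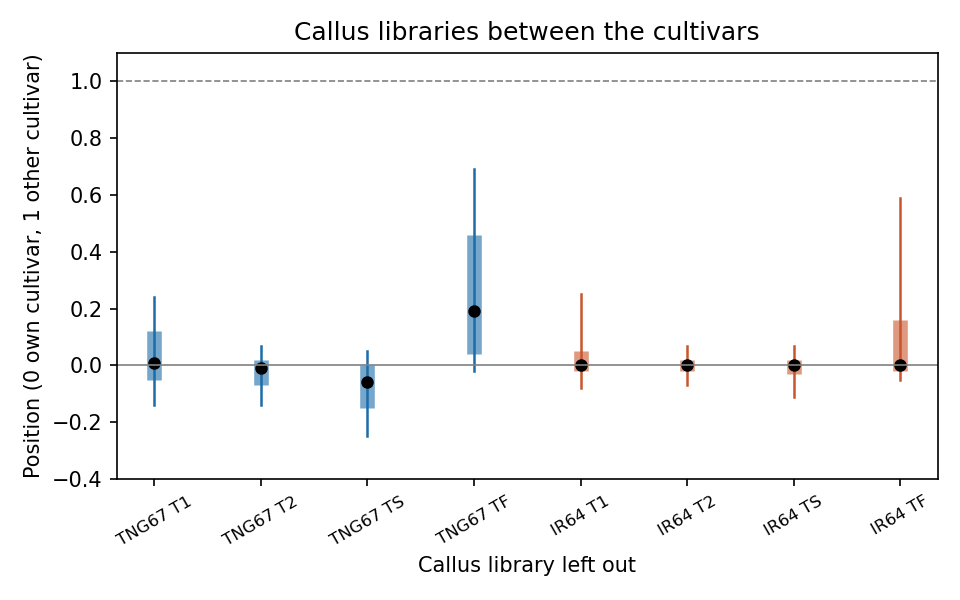
Position of each callus library between the cultivars on log2(FPKM + 1), over loci that separate the cultivars by at least 4-fold. A value of 0 is the mean of the other calli of its own cultivar, and 1 that of the calli of the other cultivar. Points are medians, thick bars the 25th to 75th and thin lines the 10th to 90th percentiles over loci; the TNG67 TF median is 0.19 and the other 7 lie at -0.06 to 0.01.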

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

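Tests of IR64 material mixed in, and of a mislabelled library, and the test of embryo tissue on the 50 most abundant loci were chosen after the results they bear on were seen; the others were written beforehand.

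Loci that were at least 4-fold higher in a stage in one cultivar and at least 4-fold lower in the other numbered 77 for T1 against T0, 101 for T2 against T0, 124 for TS against T0, 19 for TF against T0 and 42 for TS against TF. No expectation was computed for these counts, and the lists differ in size, so they do not rank the comparisons by disagreement. Loci at least 4-fold higher and lower in both cultivars numbered 514 and 875 for T1 against T0 and 335 and 757 for T2. They numbered 231 and 606 for TS, 605 and 636 for TF, and 2 and 30 for TS against TF. The difference between the cultivars was not tested at the loci that moved oppositely, because each rests on single libraries.

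The TNG67 failed callus lay between the TNG67 and the IR64 calli (median position 0.19), and much of its TF-high set was made of loci high in IR64. IR64 callus RNA or tissue mixed in was examined on 62 loci with at least 10 FPKM in the 4 IR64 calli and under 0.5 in the other TNG67 libraries. In this library 58.1% stayed under 0.05 of their IR64 level, which argues against it as the whole cause, while 23 exceeded 0.1. None of the IR64 calli left out in turn showed such a locus under 0.05. The other TNG67 libraries, tested alike on 31 to 34 loci, had 96.9 to 100% under 0.05 and 0 over 0.1. TNG67 TF thus stood apart from them. A mislabelled IR64 library is argued against by loci expressed in TNG67 alone, which kept a median of 0.768 of their TNG67 level, and scaling by a median position of 0.2 after quantile normalization. IR64 callus material as part of the cause stays open. IR64 tissue other than callus, material of another genotype, and a difference between callus cultures, which the design does not replicate, stay open and were not tested.

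Loci high in the embryo exceeded their level-matched expectation among the TF-high loci, by 2.11 times in TNG67 and 4.24 times in IR64. In TNG67 the excess was not particular to TF-high loci, as loci lower in TF than in TS had a ratio of 2.3 (0.584 in IR64). It did not hold in TNG67 at a mean of at least 5 FPKM (0.933). The TNG67 ratio was 1.09 with a pseudocount of 0.1 and 4.58 with a pseudocount of 5. The level bins changed with the pseudocount too, so these ratios are not like for like. Embryo-low loci were in greater excess in TNG67 as reported (2.8), and in lesser excess with a pseudocount of 5 (3.39 against 4.58). In IR64 the embryo-high excess ran from 2.13 to 8.59 over the settings and the embryo-low excess from 0.984 to 2.78, the latter greater at a mean of at least 5 FPKM (2.62 against 2.13). A first test of embryo tissue left in the failed calli, whose bound was set beforehand, did not decide: of 11 loci per cultivar that were abundant in the embryo and nearly silent in the other calli, 18.2% in TNG67 and 27.3% in IR64 lay more than 10-fold from the median share of their embryo level. A second test was then chosen, on the 50 most abundant embryo-high loci. These gained a median of 2.67% and 2.78% of their embryo level from TS to TF. The loci of the pattern, which were chosen for their rise in TF, gained 56.8% and 54.7%, a ratio of at most 0.0509. Evenly left-over embryo tissue that kept the transcript levels of T0 would raise both alike. The values argue only against such tissue as the main cause at the loci of the pattern. Choosing those loci for their rise also widens the contrast. A small remnant stays open. Embryo tissue whose transcript levels had changed in culture, and tissue of only part of an embryo, stay open too and were not tested. Quantile normalization left the embryo-high ratio at 2.05 in TNG67 and 4.2 in IR64, and the embryo-low ratio at 2.78 and 1.65, so scaling is argued against for either excess. The TNG67 ratio depends on the filter, is not like for like across pseudocounts and is matched by that of loci lower in TF. No pattern common to the cultivars is therefore claimed, and no biological explanation was tested.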

How the results depend on the processing

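The fits on the 8 calli, on single-row loci and of TS and TF against T2, and other settings for the overlap shares, were chosen after seeing the data. Each named locus was checked under 14 settings: of 280 checks on the 20 results past the threshold, 263 kept the call, 17 lost it and 0 reversed. The other 280 checks were of 20 results with no call to lose, and none gained one. LOC_Os08g03410 lost its call without the replicate block for TS (adjusted p = 0.066, limma) and TF against T0 (0.078), and for TS without IR64 TS (0.058); LOC_Os11g37270 lost it for TS without TNG67 TS (0.061) and without IR64 TS (0.058). Correlations between the cultivars stayed within 0.1 in 27 of 27 checks. For the 5 comparisons with calls, 67 of 101 checks of the count stayed within 1.5 times and 34 did not; for the 5 with 0 calls, 100 of 105 stayed at 0. Leaving out each library in turn gave 1439 to 7244 loci for T1 against T0, 60 to 6351 for T2, 0 to 5057 for TS, 266 to 5441 for TF, and 2430 to 8808 for TNG67 against IR64. Fewer libraries also leave fewer residual degrees of freedom. Where 1 library of a stage is left out, its partner adds nothing to the cultivar comparison or to comparisons of other stages. Leaving out either library of a stage is then nearly the same check, so the 101 checks are not independent of each other. Without the replicate block the pairing by cultivar or stage was lost, and the counts were 2504, 1509, 712, 918 and 3956. A mean of at least 5 FPKM, which tests fewer loci, gave 3434 for the cultivars. Without the filter limma called 1 locus for TS against TF, 2 for T2 against T1, 1 for regeneration medium against T2, 2 for TS against T2 and 1 for TF against T2, against 0 as reported; the cause was not tested. The 8 calli alone gave 0 for each of these. Among comparisons with the embryo the share of higher calls was 38.9 to 44.4% as deposited and 42.3 to 51.4% after quantile normalization, so the excess of lower calls for T1 (44.4% higher) turned with that scaling (51.4%).

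Counts of loci at least 4-fold moved by construction with the pseudocount and the cutoff, in the order T1, T2, TS and TF against T0, TS against TF, TS against T2 and TF against T2. With a pseudocount of 0.1 they were 5858, 5455, 4899, 5388, 1876, 491 and 1830 in TNG67 and 6014, 5629, 5340, 4517, 1588, 227 and 1549 in IR64. With a pseudocount of 5 they were 1718, 1586, 1286, 1392, 198, 18 and 183, and 1650, 1508, 1363, 1133, 240, 7 and 250. At 2-fold they were 9424, 8989, 8262, 8840, 3052, 1021 and 3148, and 9805, 9202, 8731, 7772, 2934, 567 and 2857. At a mean of at least 5 FPKM, IR64 gave 467 for TS against TF and 476 for TF against T2. Of 98 such checks 54 stayed within 1.5 times. The share of TNG67 TF-high loci that were higher in IR64 was 75.8% with a pseudocount of 0.1, 74.7% with 5 and 75.3% at a mean of at least 5 FPKM. In IR64 the embryo-high share was 50.9% with 0.1 and 53.8% at a mean of at least 5 FPKM, and the share higher in TNG67 43.2% and 45.5%; the cause was not tested. Over their level-matched expectations these overlaps moved further, in the order pseudocount of 0.1, pseudocount of 5 and mean of at least 5 FPKM. The level bins changed with the pseudocount, so part of that movement can come from how the expectation was built. The ratio for loci higher in the other cultivar was 1.78, 32.9 and 1.85 in TNG67 (5.29 as reported) and 1.26, 10.3 and 1.48 in IR64 (2.76). For embryo-high loci it was 1.09, 4.58 and 0.933 in TNG67 (2.11) and 2.41, 8.59 and 2.13 in IR64 (4.24). For embryo-low loci it was 1.35 with 0.1 in TNG67 (2.8) and 0.984, 2.78 and 2.62 in IR64 (1.66). Gene list tests fixed beforehand were not run for lack of names. Depth is unknown, so no detection limit could be set for a locus listed at 0.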

Other observations

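The tests of the japonica reference and of a general shortfall of IR64 values were chosen after the counts were seen. Loci with at least 1 FPKM in all 5 libraries of a cultivar and under 0.1 in all 5 of the other numbered 231 for TNG67 and 65 for IR64, a ratio of 3.55. At a stricter bound, at least 10 FPKM against under 0.5, they numbered 91 and 23. The TNG67 loci included 12 pairs of neighbours in locus order, where shuffled lists had a mean of 2.3 and a maximum of 9, and chromosome 12 held 29 of them. The IR64 loci included 3 pairs (shuffled mean 0.2, maximum 3). At the stricter bound there were 4 pairs for TNG67 (mean 0.4, maximum 3) and 0 for IR64 (mean 0.0, maximum 1). The median difference between the cultivars over the tested loci was 0.0023 on the log2 scale, which decides nothing about a general shortfall of IR64 values, because FPKM is scaled to the mapped fragments of each library. Loss of IR64 reads on the japonica reference would give the ratio of 3.55, and so would loci that IR64 lacks or does not express; these were not told apart.

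The TF-high loci also lay beside each other more often than shuffled lists of the same size, with 43 neighbouring pairs in TNG67 (shuffled mean 13.5, maximum 27) and 53 in IR64 (16.5, maximum 29). Loci higher in the embryo than at T2 did so as well, with 338 and 250 pairs against 172.9 and 146.4. No explanation of this was tested.

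Splits that keep the stages paired, chosen after the planned count over all splits was seen, are too few for a share under 0.05: of 16, only 1, the real one with 6261 loci, gave as many, and the highest of the others gave 0. Among 100 splits that ignore the pairing the highest other gave 1. Both leave the cultivar difference in the residual of the other splits, which keeps their counts low.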
